A study of Homo sapiens with 6 samples.

How the data were processed

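Poly(A)-enriched RNA from MNNG/HOS Cl #5 osteosarcoma cells, extracted with TRIzol, was sequenced in 3 libraries from scaffold culture (3D) and 3 from flat culture (2D) at day 7, per the labels' protocols. The authors deposited 1 table of FPKM values, fragments scaled to the length of the gene and the total of the library, for 62703 Ensembl gene IDs and the 6 libraries. FastQC, fastp, HISAT2, StringTie and edgeR and the build GRCh38 are named, without versions or roles, in the submitters' processing notes. The annotation release, the counting settings, the handling of reads that match several genes and the strandedness are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies may therefore be split in ways that cannot be seen, and FPKM values depend on the gene lengths and the library totals that were used. Genes with very many reads also lower the FPKM of all others, since reads are scaled to the total of the library. The 10 genes with most reads took 5.53 to 5.78% of each 3D library and 8.11 to 9.7% of each 2D library.

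The design fixed before the data were examined had a branch for counts and one for normalized values. The table holds FPKM, so the branch for normalized values was used, with limma. FPKM values were transformed as log2(FPKM + 1), genes with an FPKM of at least 1 in at least 3 libraries were kept (12843), and the groups were compared with limma 3.58.1 (lmFit and eBayes with trend and robust, statmod 1.5.0) in R 4.3.3, with all 6 libraries and no covariates. P-values are 2-sided with Benjamini-Hochberg adjustment, and the threshold was 0.05. Fold changes on this scale understate the change of low genes, so ratios of mean FPKM are given beside some. An exact permutation test of 3 libraries against 3 cannot go below a 2-sided p of 0.1, which is why a model across genes was used.

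There were 50 gene lists fixed before the data were examined, 43 of pathways and 7 of cell type markers. Lists with at least 5 tested members (43) were tested with camera at a preset correlation of 0.01, adjusted over these lists. Camera ranks a list against all other genes, so its direction can differ from the sign of the list's own median or mean, and it did for 10 lists, none of them called. The alternatives were a correlation estimated from the data and fry. The named genes were chosen by a rule fixed at the same time. It took the 6 genes with the largest increase and the 6 with the largest decrease among genes past the threshold with a mean of at least 5 FPKM in the higher group, no overlap between groups and a gene symbol. It also took the 3 members of each list with the smallest adjusted p (8 for the glutamine list and the amino acid transporters), and GLUL, SLC1A5, GLUD1, ABCB1, ABCC1, ABCG2, MKI67 and a further gene that is not reported here. Lists share some members, and a gene in several lists counts in each.

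Symbols came from a name table that held 62625 of the IDs, and 42300 IDs had a symbol. Positions and gene classes are those of GENCODE 29 on GRCh38, which held 58279 of the IDs. The ID of H2AC18 is not among them, so no position is given for it. For the same reason H2AC18 is left out where only protein-coding genes are tested.

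The depth of each library was worked out from the values, since an FPKM is a whole number of reads times a factor per library divided by a gene length. For all 33243 genes above 0, a length was found that gave whole reads in every library within 0.01 reads. For 11447 of them it was the exon length of GENCODE 29. Genes with reads in few libraries can meet this by chance. As a check, a length up to 20000 bases was found for 430 of 500 genes drawn from those with at least 20 reads in every library, and for 0 of 500 rows that put together values of different genes. The summed reads were 13334220, 13748880 and 16363570 in 3D replicates 1 to 3 and 14097857, 13652959 and 14241462 in 2D replicates 1 to 3, or 99.64 to 99.7% of the totals that the factors imply. A single read in a gene of 1 kb was worth 0.0609 to 0.0747 FPKM. Each pair of replicates differed by more than sampling noise (chi-square per degree of freedom of 12.9 to 28.7), so none was counted as 1 library.

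The gene test and the list test were tested on simulated data before use, with reads drawn for the 12843 genes from the real means and depths of the libraries. Each gene was given the mean spread of genes of like abundance, not its own. The changed genes and the raised list were drawn only from genes above a minimum of mean reads, so their results do not cover low genes. The gene test called 65 of 66 genes changed 4-fold, 35 of 67 changed 2-fold and 6 of 67 changed 1.5-fold, and 21 of 12187 unchanged genes. Camera called a list of 20 genes raised 1.5-fold and 0 of 42 lists of 20 unchanged genes. Reads were drawn for each gene independently, so the simulated lists held no correlation between genes, and far fewer genes were changed than were called in the data. The correlation estimated from the data was 0.622 for the hypoxia list and 0.609 for the ribosomal protein list. The simulation therefore cannot show how often camera with the preset correlation calls unchanged lists in these data.

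Alternatives fixed beforehand were a pseudocount of 0.1, no low-value filter, each library left out in turn, the replicate number as a block, the estimated correlation and fry. Chosen after seeing the data were median-ratio and upper-quartile scaling of the FPKM values, limma's voom on the worked-out reads with and without median-ratio factors, a minimum of 5 FPKM, protein-coding genes only, the mitochondrial chromosome left out and reads thinned to the shallowest library. No batch or date is named in the labels. All 6 columns of values were used. Reads were worked out with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9.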

Results

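RNA sequencing was performed on MNNG/HOS Cl #5, a human osteosarcoma cell line, after 7 days of culture in either of 2 settings. One group of 3 libraries came from cells seeded inside a scaffold of demineralised bone matrix, called 3D here, and the other group of 3 came from cells grown flat, called 2D. The series title names drug resistance inside the scaffold and glutamine metabolism, so the comparison asks how the transcriptome of the scaffold culture differed from that of the flat culture and how genes of glutamine use and drug handling stood within it. The deposited table gives FPKM values, from which 13334220 to 16363570 reads per library were worked out in 3D and 13652959 to 14241462 in 2D. Of the genes in the table, 12843 reached an FPKM of 1 in at least 3 libraries and were tested. Libraries of the same group correlated at 0.968 to 0.981 over these genes, a correlation across genes, and libraries of different groups at 0.886 to 0.92. The first principal component held 72.7% of the variance and parted the groups. On the second, which held 10.2%, 3D replicate 1 lay apart from the other 3D libraries (20.9 against -5.7 and -16). There 2D replicate 3 also lay apart from the other 2D libraries (-14.3 against 9.2 and 6).

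In the scaffold, genes of DNA replication, ribosome biogenesis genes with MYC targets, and genes of one-carbon metabolism were higher. Targets of the hypoxia-inducible factors, glycolytic genes and cytosolic ribosomal protein genes were lower. These 6 list calls rest on a preset correlation between genes and were lost with an estimated correlation. Camera then gave an adjusted p of 0.807 for ribosome biogenesis and MYC targets and 0.659 for the others. THBS1, which encodes the secreted matrix glycoprotein thrombospondin 1, was 7.59-fold higher in 3D by the ratio of mean FPKM (35.1 ± 5.54 against 4.63 ± 0.844, SD, n = 3 each). TXNIP, which encodes a thioredoxin-binding protein that restrains glucose uptake, was 45.2-fold lower (3.18 ± 0.568 against 143.8 ± 34.8). In all, 4272 genes rose and 2328 fell in 3D at a limma adjusted p under 0.05, and 6243 did not pass. Of these, 709 rose and 532 fell by at least 2-fold on the log2(FPKM + 1) scale, against 1449 and 914 with a pseudocount of 0.1 and 1542 and 951 with voom on the worked-out reads. The 3 libraries of one group lay wholly above those of the other for 60.9% of the tested genes, where 10% is expected for genes without a difference. Genes vary together, so the share could lie far from 10% by chance and is not a test. The split of calls depended on the scaling of the libraries, since median-ratio factors gave 3155 genes higher and 3146 lower, and 434 higher and 795 lower by 2-fold. That scaling, chosen after seeing the data, moved the median log2 change of all tested genes from 0.144 to 0.008.

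**Figure D1:**
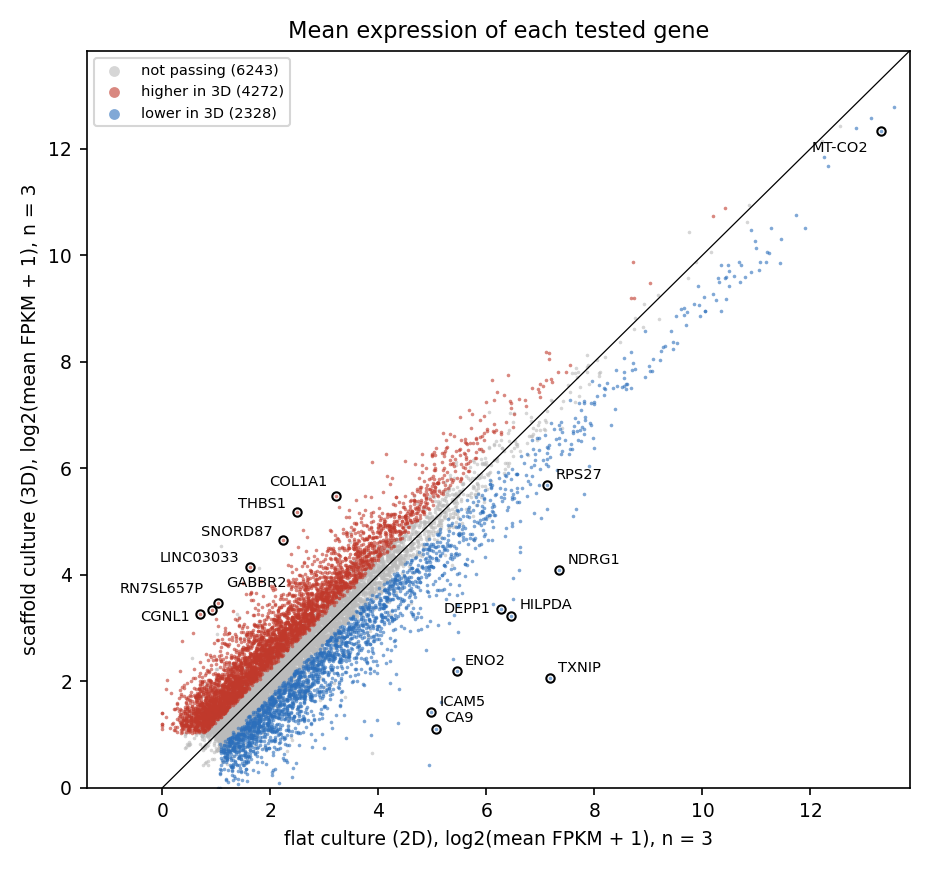
Mean expression of the 12843 tested genes in flat culture (horizontal axis) and scaffold culture (vertical axis), both as log2(mean FPKM + 1) over 3 libraries; the line marks equal means, red points are the 4272 genes higher in 3D, blue points the 2328 lower and grey points the 6243 not passing. TXNIP lies farthest below the line among the circled genes, with means of 143.8 in 2D and 3.18 in 3D.

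Among genes with a mean of at least 5 FPKM in the higher group, the 6 with the largest fitted increase in 3D were THBS1, SNORD87, RN7SL657P, LINC03033, CGNL1 and GABBR2. THBS1 (chromosome 15, 39581079 to 39599466, GRCh38, as are all positions here) had a log2 change of 2.68 (SE 0.16, limma adjusted p = 0.000192). GABBR2 (chromosome 9, 98288082 to 98709197), a subunit of the metabotropic GABA receptor, rose from 1.04 ± 0.34 to 10.1 ± 0.319 FPKM (log2 change 2.45, SE 0.13). CGNL1 (chromosome 15, 57375967 to 57550727), the junction protein paracingulin, rose from 0.625 ± 0.22 to 8.56 ± 3.84 FPKM. The long noncoding RNA LINC03033 (chromosome 14, 61570540 to 61658696) rose from 2.08 ± 1.4 to 16.8 ± 6.63 FPKM. SNORD87 (chromosome 8, 66922467 to 66922555), a small nucleolar RNA gene of 89 bases, rested on 29 to 36 reads per 3D library and 1 to 9 per 2D library. RN7SL657P (chromosome 1, 1405460 to 1405752), a copy of the 7SL RNA gene, rested on 31 to 45 and 1 to 9 reads, and reads from other copies may be counted on it. Small RNA genes without a poly(A) tail, the class of SNORD87, took 1116 ± 290.4 RPM in 3D and 792.6 ± 158.3 RPM in 2D. Small nuclear RNA genes took 60.7 to 146.5 RPM in 3D and 39.3 to 46.7 in 2D, and genes annotated as sense intronic 447.8 to 514.6 and 327.8 to 396.7. The spans of THBS1, CGNL1 and LINC03033 overlap those of 3, 3 and 2 other annotated genes and those of SNORD87, RN7SL657P and GABBR2 overlap 1 each, and strand is not stated for the counting, so reads of these may be included.

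The 6 genes with the largest fitted decrease were TXNIP, CA9, NDRG1, ICAM5, DEPP1 and ENO2. TXNIP (chromosome 1, 145992435 to 145996600) had a log2 change of -5.10 (SE 0.19, limma adjusted p = 9.29e-05). CA9 (chromosome 9, 35673856 to 35681159), the carbonic anhydrase induced by low oxygen, fell from 32.5 ± 5.47 to 1.16 ± 0.905 FPKM. NDRG1 (chromosome 8, 133237171 to 133302022), a stress-responsive gene also induced by low oxygen, fell from 162.2 ± 8.06 to 16.0 ± 11.7 FPKM (log2 change -3.64, SE 0.64). ICAM5 (chromosome 19, 10289981 to 10296778), a cell adhesion molecule, fell from 30.6 ± 1.42 to 1.69 ± 0.296 FPKM. DEPP1 (chromosome 10, 44970981 to 44978810), a FOXO target, fell from 76.3 ± 10.2 to 9.22 ± 8.35 FPKM. ENO2 (chromosome 12, 6913745 to 6923698), an enolase of glycolysis, fell from 42.8 ± 6.02 to 3.58 ± 1.32 FPKM. 3D replicate 1 held the lowest values of CA9, NDRG1 and DEPP1, with 3, 851 and 25 reads. Without it the log2 changes of NDRG1 and DEPP1 were -2.82 and -2.44, and without 3D replicate 3 that of DEPP1 was -4.24.

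Hypoxia targets fell almost as a block. Of 33 tested members of the list of hypoxia and HIF targets, 30 fell, none rose and 3 did not pass, with 31 lower when adjusted over the list alone. The median log2 change was -1.55, and the list was called lower (camera adjusted p = 5.81e-16 with a preset correlation, adjusted p = 0.659 with an estimated correlation). HILPDA, which encodes a lipid droplet protein, fell from 87.2 ± 4.09 to 8.4 ± 2.52 FPKM, CA12, another carbonic anhydrase, from 5.78 ± 0.666 to 1.03 ± 0.0543, and MXI1, which encodes a MAX-binding antagonist of MYC, from 3.26 ± 0.224 to 0.285 ± 0.0273. Without 3D replicate 1, 30 members were lower and the median was -1.26. In the glycolysis list, 14 of 22 members fell and 2 rose (14 became 15 when adjusted over the list alone), with a median of -0.58 (adjusted p = 3.47e-06, and 0.659 with an estimated correlation). ALDOA, fructose-bisphosphate aldolase, fell from 184.6 ± 12.3 to 76.6 ± 4.99 FPKM, and HK2, the hexokinase that commits glucose to the pathway, from 62.3 ± 5.8 to 19.1 ± 4.08. Of the tricarboxylic acid cycle list, 18 of 28 members rose and 1 fell (20 and 1 when adjusted over the list alone), with a median of 0.42 (adjusted p = 0.00921, and 0.659 with an estimated correlation). DLD and DLAT, subunits of the pyruvate dehydrogenase complex, had log2 changes of 0.98 and 0.98, whereas IDH2, the mitochondrial NADP-dependent isocitrate dehydrogenase, fell by 1.18. With a minimum of 5 FPKM, chosen after seeing the data, the call of this list was lost (adjusted p = 0.0532).

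Replication genes rose almost throughout. In the list of DNA replication and G1/S, 39 of 41 members rose, none fell and 2 did not pass, the same counts as when adjusted over the list alone, with a median log2 change of 1.26 (camera adjusted p = 1.16e-12, and adjusted p = 0.659 with an estimated correlation). MCM3 and MCM10, factors of the replicative helicase, rose from 8.68 ± 0.323 to 37.8 ± 4.3 FPKM and from 2.32 ± 0.155 to 11.6 ± 1.24, and CLSPN, the checkpoint adaptor claspin, rose from 1.95 ± 0.146 to 8.83 ± 0.732. The list of mitosis and G2/M had 25 of 41 members higher and 3 lower (25 and 3 when adjusted over the list alone), with a median of 0.34 (adjusted p = 0.0137, and 0.659 with an estimated correlation). KIF11, a spindle motor, rose from 15.0 ± 1.13 to 28.3 ± 1.47 FPKM, KIF23 and NDC80 rose by log2 changes of 0.70 and 0.74, and the call of the list was lost with median-ratio scaling (adjusted p = 0.0593). MKI67, the proliferation marker, did not pass, at 40.7 ± 6.43 against 33.6 ± 5.47 FPKM (limma adjusted p = 0.198). In the list of ribosome biogenesis and MYC targets, 22 of 32 members rose and none fell (23 and 1 when adjusted over the list alone), with a median of 0.845 (adjusted p = 0.00041, and 0.807 with an estimated correlation). UTP20, a factor of small-subunit assembly, rose from 1.92 ± 0.399 to 11.5 ± 0.692 FPKM, and POLR1A, the largest subunit of RNA polymerase I, from 1.61 ± 0.288 to 7.88 ± 0.806.

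The genes for the cytosolic ribosomal proteins themselves went the other way. Of 73 tested, 66 fell, 1 rose and 6 did not pass, with 68 lower and 1 higher when adjusted over the list alone, and the median log2 change was -0.82 (camera adjusted p = 1.29e-21, and adjusted p = 0.659 with an estimated correlation). RPS27 fell from 138.3 ± 21 to 50.5 ± 1.42 FPKM, RPL29 from 191.2 ± 13.7 to 81.7 ± 3.56 and RPL37 from 157.0 ± 22.7 to 61.6 ± 5.39. The exception was RPS26, named after its values were seen, at 4.02 ± 1.05 in 3D and 2.35 ± 0.131 in 2D, whose call was lost with median-ratio scaling (adjusted p = 0.0502). These genes have many processed pseudogenes, and how reads were split between them is not stated in the sources used here, so single values are uncertain. Processed pseudogenes took 3.58 to 3.98% of the reads of each 3D library and 4.92 to 5.99% of each 2D library, and small nuclear and sense intronic RNA, given above, stood the other way. Of the 13 mitochondrially encoded genes, 6 fell and 2 rose, also when adjusted over the list alone (median -0.19, adjusted p = 0.0144, and 0.724 with an estimated correlation). MT-CO2, a subunit of cytochrome c oxidase, had a log2 change of -0.97, and mitochondrial reads made up 4.28 to 4.57% of each 3D library and 5.86 to 7.21% of each 2D library. Chaperone genes of the endoplasmic reticulum fell in 9 of 22 cases and rose in 2, the same counts as when adjusted over the list alone (median -0.28, adjusted p = 0.00687, and 0.659 with an estimated correlation), and HSP90B1, CALR and MANF had log2 changes of -0.96, -0.63 and -0.64.

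**Figure D2:**
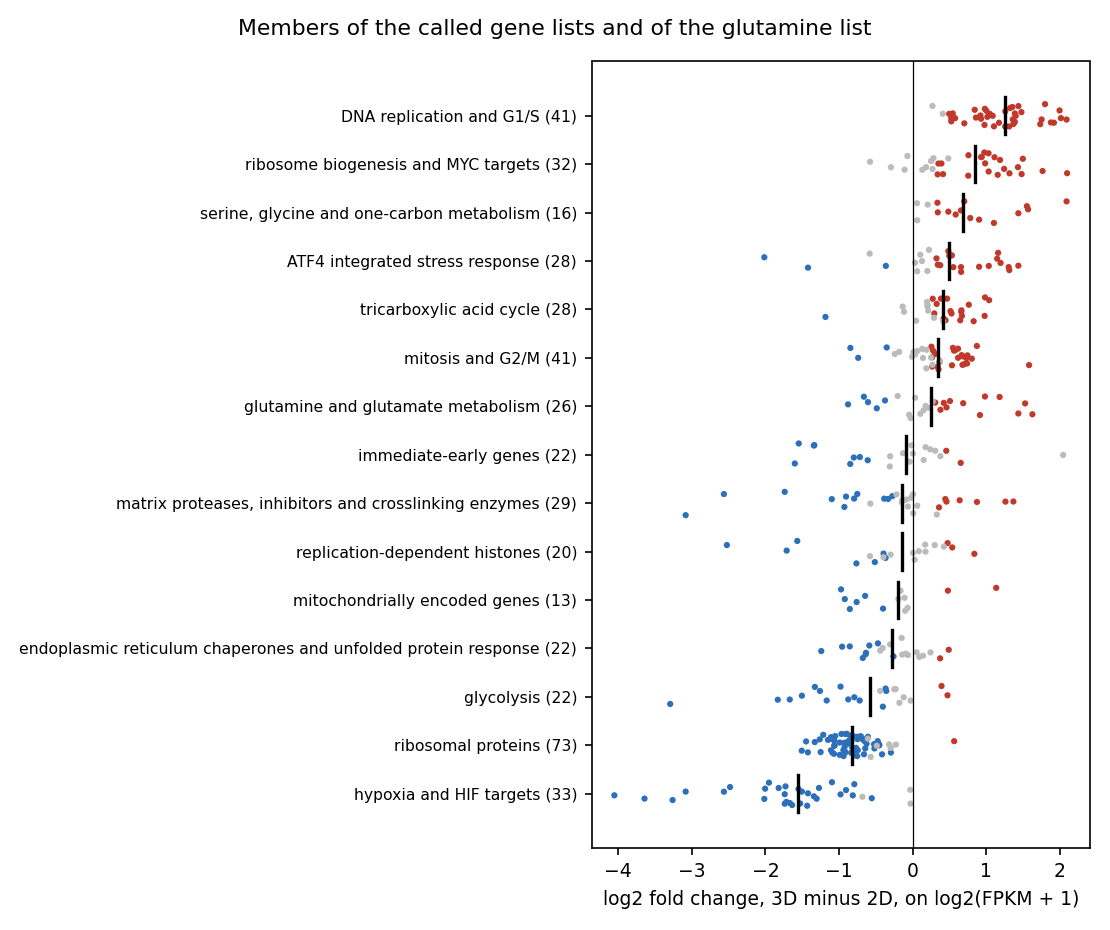
Log2 change of each tested member of the 14 called gene lists and of the glutamine list (3D minus 2D on the log2(FPKM + 1) scale, horizontal axis); red points are members higher and blue points members lower at a limma adjusted p under 0.05, grey points did not pass, bars are medians and the number of tested members follows each name. Medians run from -1.55 for the hypoxia targets to 1.26 for DNA replication.

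Genes of glutamine and glutamate metabolism moved in both directions, and their list was not called. Of its 26 tested members, 12 rose, 5 fell and 9 did not pass, with 13 higher and 5 lower when adjusted over the list alone. The median log2 change was 0.245, and camera gave an adjusted p of 0.351 (0.836 with an estimated correlation), while fry, which asks whether the members move one way and does not compare them with other genes, gave an adjusted p of 0.00805. With median-ratio scaling 9 members rose and 5 fell and the median was 0.095, and with upper-quartile scaling it was 0.106. PFAS, an enzyme of purine synthesis, rose from 5.46 ± 0.643 to 18.9 ± 1.06 FPKM (log2 change 1.63, SE 0.11, limma adjusted p = 0.000228). CTPS1, which makes CTP, rose from 1.77 ± 0.277 to 7.01 ± 1.03, CAD, which starts pyrimidine synthesis, from 7.7 ± 0.754 to 18.8 ± 2.22, and GMPS, which makes GMP, from 12.3 ± 1.14 to 20.4 ± 1.07. CTPS2, which also makes CTP and was named after its values were seen, did not pass (log2 change -0.05, adjusted p = 0.685). The aspartate transaminases GOT1 and GOT2 had log2 changes of 0.92 and 0.98, and PSAT1, the transaminase of serine synthesis, rose from 35.6 ± 5.3 to 100.2 ± 30.4 FPKM, whereas GGT7, a member of the gamma-glutamyltransferase family, fell from 12.5 ± 0.741 to 7.55 ± 0.606. GLUL, glutamine synthetase, was at 7.0 ± 0.962 against 5.13 ± 0.383 (adjusted p = 0.0301), a call lost with median-ratio scaling (adjusted p = 0.139), with no low-value filter (0.0722) and without 3D replicate 1 or 3 or 2D replicate 1 or 2 (0.0785, 0.0886, 0.0863 and 0.0859). GLUD1, glutamate dehydrogenase, did not pass, at 3.04 ± 0.32 against 3.72 ± 1.08 FPKM.

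**Figure D3:**
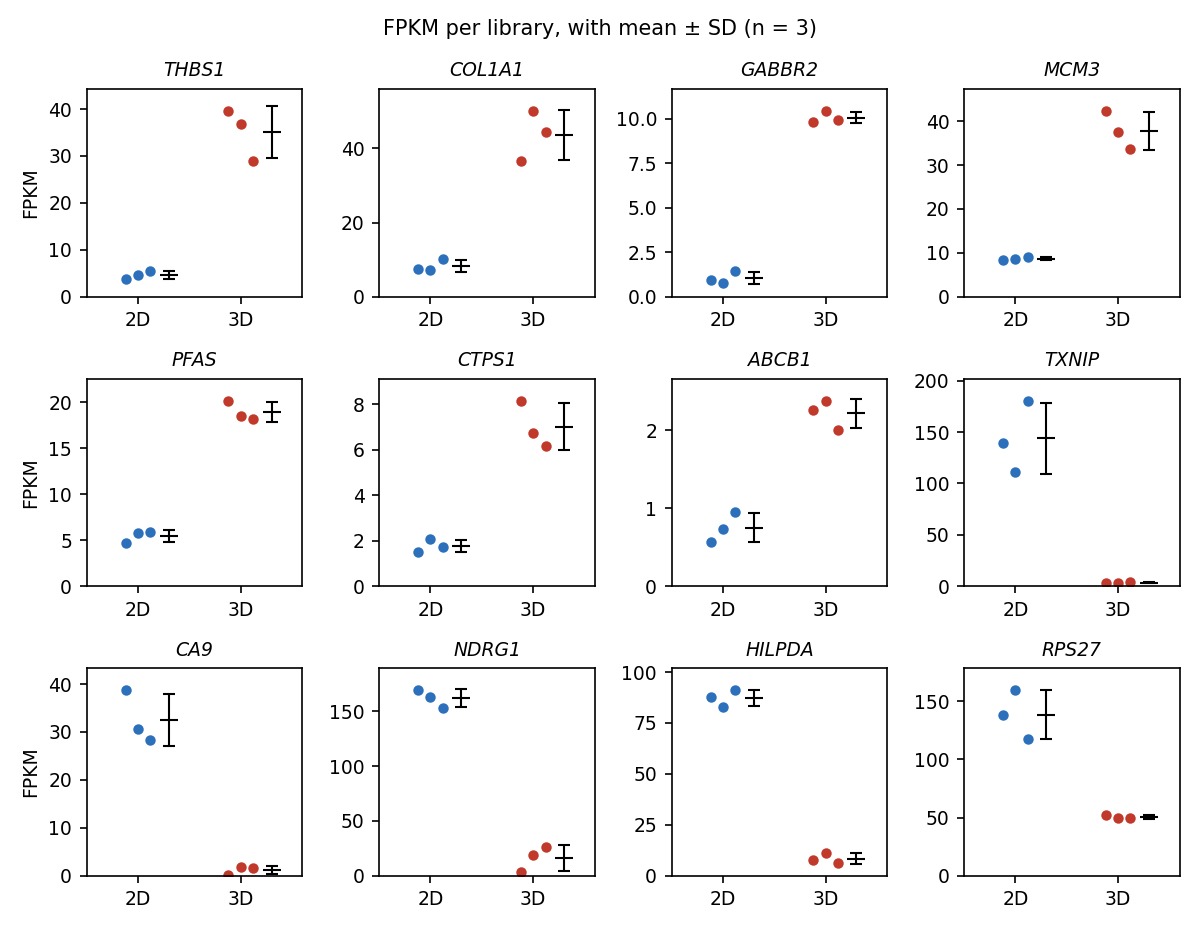
FPKM of 12 named genes in each of the 3 flat (2D, blue) and 3 scaffold (3D, red) libraries, with the mean ± SD in black; every vertical axis starts at 0. For PFAS the 3D mean is 18.9 and the 2D mean 5.46, and for CTPS1 7.01 and 1.77.

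Of 16 glutamine and amino acid transporters, 6 rose, 3 fell and 7 did not pass, also when adjusted over the list alone, and the list was not called (median 0.32, camera adjusted p = 0.936). With median-ratio scaling 5 rose and 5 fell. SLC38A1, a glutamine importer, rose from 16.9 ± 2.54 to 32.9 ± 4.01 FPKM, SLC7A1, which imports cationic amino acids, from 18.6 ± 2.37 to 34.5 ± 0.798, and SLC7A11, the cystine and glutamate exchanger, from 13.2 ± 3.22 to 28.2 ± 7.68. SLC36A1 and SLC38A7 had log2 changes of 1.08 and 0.65. SLC1A1, a glutamate importer, fell from 3.75 ± 0.274 to 0.55 ± 0.228, and SLC7A8 and SLC7A6 had log2 changes of -0.72 and -0.49. The call of SLC7A6 was lost without 3D replicate 2 or 3 or 2D replicate 1 (adjusted p = 0.0564, 0.0635 and 0.0514) and with no low-value filter (0.058). SLC1A5, the main glutamine importer of many cancer cells, was at 52.6 ± 10.2 against 36.6 ± 8.55 and did not pass (limma adjusted p = 0.0731). The serine, glycine and one-carbon list was called higher, with 13 of 16 members higher and none lower, also when adjusted over the list alone (median 0.68, adjusted p = 0.0012, and 0.659 with an estimated correlation). MTHFD1, a folate enzyme, rose from 5.02 ± 0.362 to 17.0 ± 2.26 FPKM, MAT2A, which makes S-adenosylmethionine, from 18.1 ± 1.73 to 55.2 ± 7.97, and TYMS, thymidylate synthase, from 36.5 ± 2.85 to 79.6 ± 6.98. In the ATF4 list, 18 of 28 members rose and 3 fell (19 and 4 when adjusted over the list alone, median 0.49, adjusted p = 0.0459, and 0.724 with an estimated correlation). The synthetase genes MARS1 and WARS1 and the transcription factor gene CEBPG had log2 changes of 1.16, 1.31 and 1.20, whereas ATF4 itself, named after its values were seen, was lower, at 11.4 ± 0.994 against 15.0 ± 1.72 FPKM (limma adjusted p = 0.0331). The call of the list was lost with median-ratio scaling (adjusted p = 0.0539), with a minimum of 5 FPKM (0.0871), with protein-coding genes alone (0.0617) and without 3D replicate 3, 2D replicate 1 or 2D replicate 3 (0.0528, 0.0913 and 0.108).

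Drug-handling genes moved in both directions, and their list was not called. Of 22 tested, 11 rose, 4 fell and 7 did not pass, also when adjusted over the list alone (median 0.27, camera adjusted p = 0.276). Fry, which does not compare the members with other genes, called the list higher (adjusted p = 0.00245). With median-ratio scaling 10 rose and 4 fell and the median was 0.113. ABCB1, the P-glycoprotein efflux pump (chromosome 7), rose from 0.75 ± 0.189 to 2.21 ± 0.191 FPKM (log2 change 0.88, SE 0.11, limma adjusted p = 0.000937). ABCC5, another efflux pump, rose from 1.09 ± 0.0861 to 3.21 ± 0.133, and ALDH1B1, an aldehyde dehydrogenase, from 6.85 ± 0.752 to 18.2 ± 3.4, whereas ABCA3, a lipid transporter linked to drug sequestration, fell from 6.95 ± 0.335 to 1.89 ± 0.286. ABCC1 did not pass, at 5.8 ± 0.763 against 4.67 ± 0.719 (adjusted p = 0.134). ABCG2 lay under the filter and was not tested, at 0.124 ± 0.0924 against 0.0918 ± 0.018 FPKM with 11 to 32 reads per library. Among 8 genes that oppose apoptosis, 4 rose and none fell (4 and 1 when adjusted over the list alone, 2 and 1 with median-ratio scaling), including BCL2L1, from 1.66 ± 0.376 to 4.25 ± 0.881 FPKM, and BIRC5, with a log2 change of 0.67. BIRC6 was at 12.2 ± 2.06 against 7.89 ± 1.44, a call lost with median-ratio scaling (adjusted p = 0.0664), with no low-value filter (0.0685) and without 3D replicate 2 or 3 or 2D replicate 1 or 2 (0.0665, 0.0693, 0.0698 and 0.0657). Of 18 genes that promote it, 5 rose and 3 fell, also when adjusted over the list alone, and 3 rose and 3 fell with median-ratio scaling; BAK1 and CYCS had log2 changes of 0.94 and 1.00 and BBC3 one of -1.35. Neither list was called by camera (adjusted p = 0.694 for both), and fry called the first higher (adjusted p = 0.0222).

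Among 16 collagens, 2 rose and 6 fell, also when adjusted over the list alone, and the list was not called (median -0.14, camera adjusted p = 0.147). COL1A1, the main collagen of bone, rose from 8.28 ± 1.61 to 43.7 ± 6.75 FPKM, whereas COL6A2 fell from 250.7 ± 14.9 to 93.4 ± 13.5 and COL6A1 from 163.8 ± 9.42 to 106.1 ± 7.43. Of 29 matrix proteases, inhibitors and crosslinking enzymes, 11 fell and 7 rose (12 and 7 when adjusted over the list alone), and the list was called lower (median -0.14, adjusted p = 0.0398, and 0.807 with an estimated correlation). P4HA1 and P4HA2, prolyl hydroxylases of collagen that are also in the hypoxia list, fell from 89.6 ± 10.2 to 14.4 ± 2.39 FPKM and from 14.1 ± 1.02 to 3.56 ± 0.848, and TGM2, a transglutaminase, rose from 3.24 ± 0.149 to 9.96 ± 0.79. The call was lost with median-ratio scaling (adjusted p = 0.0754), with a minimum of 5 FPKM (0.0532), with no low-value filter (0.0608) and without 3D replicate 1, 2D replicate 2 or 2D replicate 3 (0.0863, 0.126 and 0.0504). Of 22 immediate-early genes, 8 fell and 2 rose, also when adjusted over the list alone (median -0.085, adjusted p = 0.027, and 0.659 with an estimated correlation but 0.0849 without 3D replicate 1 and 0.182 with a minimum of 5 FPKM). EGR1, JUNB and DUSP1 had log2 changes of -1.34, -1.55 and -1.60.

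Histone genes of the replication-dependent class fell in 7 of 20 cases and rose in 3, also when adjusted over the list alone (median -0.15, camera adjusted p = 0.0483, and 0.659 with an estimated correlation). The libraries were poly(A)-enriched, so these values cover polyadenylated histone transcripts and carry-over of those without a tail, not all histone RNA. H2AC18 fell from 96.8 ± 12.1 to 16.0 ± 1.49 FPKM, H1-2 from 116.6 ± 24.0 to 35.0 ± 8.23 and H2BC21 from 26.8 ± 6.0 to 8.24 ± 0.514. H2AC18 has a near-identical copy in H2AC19, so their values cannot be read apart, and the 3 genes that rose, H2BC12, H4C3 and H4C4, were named after their values were seen and lost their calls with median-ratio scaling (adjusted p = 0.0912, 0.0901 and 0.064). The call was lost with median-ratio scaling (adjusted p = 0.0914), with a minimum of 5 FPKM (0.0693), with protein-coding genes alone (0.0964), with no low-value filter (0.0842, where the median was 0.028) and without 3D replicate 2 or 2D replicate 3 (0.0869 and 0.0501). H2AC18 has no gene class in the annotation used, so the setting with protein-coding genes alone left it out. The loss of the call in that setting may come from this omission and says nothing about coding genes as such. Markers of other cell types were few: 5 haematopoietic markers were tested, of which CD68 fell from 19.1 ± 2.73 to 3.42 ± 0.93 FPKM, ITGB2 fell by 0.44 on the log2 scale and LAPTM5 rose from 32.8 ± 3.03 to 51.6 ± 1.87 (list adjusted p = 0.359). The haemoglobin genes HBA1, HBA2 and HBB did not pass, with means of 2.27, 0.858 and 1.41 FPKM in 3D and 9.41, 4.28 and 4.74 in 2D. They were called lower without 2D replicate 3 (adjusted p = 0.00622, 0.00583 and 0.00616). Of 4 epithelial markers, KRT8 and KRT18 rose and CLDN3 fell, with log2 changes of 0.83, 0.74 and -1.55. Single endothelial and adipocyte markers, ESAM and PPARG, did not pass, and no osteoclast or skeletal muscle marker reached the filter. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. No list was called with an estimated correlation, so list calls rest on the preset correlation. Other groupings of the 6 libraries into 3 and 3, which mix both cultures in each group, gave up to 9 called lists in a direction.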

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

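The scalings, voom, the minimum of 5 FPKM, the restrictions to gene classes and the thinning were chosen after seeing the data. Of 154 called named genes, 149 kept direction and call under every alternative that tested them, and none changed direction; SLC7A6, BIRC6, BMP6, MT1M and GLUL lost the call under some. Genes higher in 3D ranged from 2910 to 4059 and genes lower from 1721 to 2162 with 1 library left out, 2-fold increases from 548 to 771 and 2-fold decreases from 396 to 556, lists higher from 5 to 6 and lower from 6 to 8, and the median of the glutamine list from 0.214 to 0.342. A minimum of 5 FPKM, which tests fewer genes (5715), gave 2134 genes higher, 1319 lower, 437 higher by 2-fold and 5 lists lower. Protein-coding genes alone gave 351 lower by 2-fold, also with fewer tested. A pseudocount of 0.1, which shrinks folds of low genes less, gave 1449 and 914 2-fold changes, and voom, which uses no FPKM pseudocount, gave 1542 and 951 (1309 lower with median-ratio factors). Median-ratio and upper-quartile scaling moved all changes down and gave 434 and 444 2-fold increases and 795 and 773 2-fold decreases, so that decreases outnumbered increases. Median-ratio scaling left 5483 of the 6600 calls in the same direction and called none in the opposite one. It turned the sign of the median of 7 lists, none of them called. With an estimated correlation 0 lists were called higher and 0 lower, and fry called 20 higher and 9 lower; it called the glutamine list higher (median 0.245, adjusted p = 0.00805), whose adjusted p ranged from 0.155 to 0.836 and whose median from 0.095 to 0.343 under the other alternatives. For the glutathione and NRF2 redox genes (median 0.073, adjusted p = 0.0258) and the TGF-beta list (median -0.024, adjusted p = 0.0314), both uncalled by camera and ranked lower than other genes, fry called an increase; the tests answer different questions. The replicate number as a block gave 4291 genes higher and 2382 lower, 5 lists higher and 8 lower, and ended the calls of the ATF4 and histone lists (both adjusted p = 0.0538) while calling the cell cycle inhibitor list (0.047). Whether the numbers pair the libraries cannot be told from 3 libraries per group. Deviations of same-numbered libraries from their group means correlated at 0.084, -0.017 and 0.184, the last being the highest of all. Those of libraries with different numbers correlated at -0.172 to 0.104, and 3D replicate 1 correlated best with 2D replicate 2 (0.104). Alternatives that need deposited counts (other size factors in a count model, a second count test, count filters) were not run on FPKM. Depth limits low genes most, since 1 read was worth up to 0.0747 FPKM in a gene of 1 kb.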

Other observations

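The tests of explanations and the lists added to them were chosen after the results were seen, except the regroupings of the libraries. For the tests on GC content and length of the hypoxia targets and on mitochondrial ribosomal proteins, the expected outcomes were written before the tests were run. Both follow up patterns seen in these data, and the mitochondrial ribosomal list was not among those fixed beforehand. Of 18 interferon-response genes, 10 rose in 3D and 3 fell, but the list was not called (median log2 change 0.581, camera adjusted p = 0.216). Without 3D replicate 1, 13 were tested, of which 5 rose and 4 fell, with a median of 0.3. IFI44 rose from 1.03 ± 0.0646 to 5.86 ± 2.08 FPKM (SD, n = 3), IFIT3, an antiviral effector, from 0.373 ± 0.0288 to 2.93 ± 1.07, and USP18, which damps interferon signalling, by a log2 change of 0.75. Fatty acid synthesis genes rose in 7 of 14 cases and fell in none (adjusted p = 0.171), led by FASN, fatty acid synthase, from 69.2 ± 10.0 to 155.3 ± 17.6, and ACLY, which makes cytosolic acetyl-CoA, from 36.0 ± 7.84 to 73.9 ± 4.28. In the cholesterol list 3 rose and 5 fell (adjusted p = 0.276), or 2 and 8 with median-ratio scaling: MSMO1 fell from 57.1 ± 5.57 to 22.5 ± 3.14, and LSS and ACAT2 rose by log2 changes of 1.08 and 0.68. Heat shock genes rose in 9 of 17 cases and fell in 1 (adjusted p = 0.171), or 5 and 1 with median-ratio scaling, with HSPH1, HSPA4 and DNAJA1 at log2 changes of 0.96, 0.94 and 0.94. Of 10 cell cycle inhibitors, 5 fell and 2 rose (adjusted p = 0.0527). This list was called lower with a pseudocount of 0.1 (adjusted p = 0.0492), no low-value filter (0.0214), protein-coding genes alone (0.0493), without 2D replicate 2 or 3 (0.0369 and 0.0469) and by fry (0.0042). CDKN2D and BTG1 fell by 0.82 and 1.11 on the log2 scale, whereas the pocket protein gene RBL1 rose by a log2 change of 1.40.

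Of 23 YAP and TEAD targets, 9 rose and 2 fell (adjusted p = 0.447), with FJX1 and AMOTL2 at log2 changes of 1.72 and 1.02 and IGFBP3 at -1.48. Among 11 stemness genes 5 rose and none fell (adjusted p = 0.572), but 5 rose and 2 fell without 3D replicate 1, and NES, which encodes the intermediate filament nestin, rose from 11.5 ± 0.729 to 34.7 ± 2.03 FPKM. Of 12 NF-kB and cytokine genes 5 fell and 3 rose (adjusted p = 0.276), with IL11 falling from 18.6 ± 0.15 to 8.03 ± 0.0479. Of 14 angiogenic growth factors 5 fell and 4 rose (adjusted p = 0.341), or 5 and 2 of 12 without 3D replicate 1, with PDGFB, VEGFB and PDGFA at log2 changes of -2.53, -1.01 and -1.37. Of 23 genes of TGF-beta response and mesenchymal transition 7 rose and 3 fell (adjusted p = 0.844), but 4 rose and 6 fell with median-ratio scaling and 5 rose and 5 fell without 3D replicate 1, and VIM, vimentin, fell from 598.1 ± 127.2 to 294.5 ± 2.87. Of 13 osteoblast genes 3 rose and 2 fell (adjusted p = 0.694), or 2 and 2 with median-ratio scaling, VDR among the first with a log2 change of 1.08. Each of these lists and those of the paragraph above had an adjusted p over 0.65 with an estimated correlation. Unlike camera, fry called the interferon, fatty acid synthesis, heat shock, YAP, stemness, osteoblast, TGF-beta, actin, p53, Wnt and redox lists higher and the cell cycle inhibitor and NF-kB lists lower (adjusted p of 0.00245 to 0.0314 for the first and 0.0042 and 0.0199 for the others). Of the lists not yet described, none was called by camera. The nuclear-encoded oxidative phosphorylation genes had 9 of 62 higher and 11 lower, the redox genes 13 of 37 higher and 4 lower, the lysosome and autophagy genes 6 of 28 higher and 10 lower, and the integrin and focal adhesion genes 9 of 30 higher and 7 lower. Fatty acid oxidation had 7 of 17 higher and 3 lower, other matrix proteins 10 of 26 and 6, p53 targets 7 of 21 and 3, actin and SRF targets 7 of 18 and 2, Wnt genes 7 of 16 and 2, Notch genes 2 of 9 and 3, metallothioneins 1 of 6 and 0, and chondrocyte genes, too few to test, 2 of 4 and 1. For the metallothioneins these were 0 and 0 when adjusted over the list alone or with median-ratio scaling, and 0 and 2 without 3D replicate 1. The median, the mean and the direction of camera did not share a sign for the redox, pro-apoptotic, other matrix, integrin, TGF-beta, oxidative phosphorylation, fatty acid oxidation, lysosome, Notch and metallothionein lists. With median-ratio scaling 7 redox genes were higher and 8 lower, 5 and 18 oxidative phosphorylation genes, 5 and 11 integrin genes, 7 and 9 other matrix genes and 3 and 5 fatty acid oxidation genes. Without 3D replicate 1 the redox list had 7 higher and 5 lower and fatty acid oxidation 4 and 4. With that scaling the median changed sign for the redox, pro-apoptotic, integrin, oxidative phosphorylation, p53, lysosome and Notch lists.

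The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 4272 genes higher and 2328 lower, with 709 and 532 by 2-fold. Any other split gave at most 1 gene in either direction, so for each count only 1 of the 10 splits, the real split, gave as many. Every other split has libraries of both cultures in each group. The difference between the cultures then adds to the spread within groups, so few gene calls were bound to result there. For lists, the real split gave 6 higher and 8 lower. Counted in either direction, the highest other split gave 9 for both, and 6 and 4 of the 10 splits gave as many. Those splits still hold part of the difference between the cultures, so they do not show how many lists would be called without it. For the median of the glutamine list, 0.245 in the real split and at most 0.184 in size in the others, 1 split gave as much.

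The hypoxia targets lower in 3D (adjusted p = 0.659 with an estimated correlation) are a pattern that runs against the thought that cells inside a scaffold receive less oxygen. With median-ratio factors the median of the list was lower still, at -1.717 against -1.552, so the choice between these scalings does not account for the fall. Those factors moved the median of all tested genes only from 0.144 to 0.008, far less than this fall. A bias of GC content or length is argued against, since the lowest median of 10000 lists matched on GC content, length and abundance was -0.328 against -1.552 for the list. 3D replicate 1, whose omission moved the list most, does not account for it either, since with any one 3D library left out the median was at most -1.261. What stays open is the cultures themselves: a denser flat culture at day 7, with less oxygen or nutrient per cell, may be as good a candidate explanation as a change made by the scaffold, and oxygen and cell density were not measured here.

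Ribosomal protein genes were lower in 3D while ribosome biogenesis genes and MYC targets were higher, both by camera with a preset correlation. With an estimated correlation camera gave an adjusted p of 0.659 and 0.807. With median-ratio factors the median of the ribosomal protein list was -0.999, and the lowest of 10000 lists matched on length and abundance was -0.251, against -0.824 for the list. Reads did not move to pseudogene copies, since genes and pseudogenes together took 0.56 times as many RPM in 3D. Of 18 other genes with a 5' TOP motif, a sequence read by the mTOR pathway, 8 fell and 1 rose. Their median was -0.306 (camera adjusted p = 0.000476 over the added lists alone, and 0.454 with an estimated correlation). TPT1 and GAS5 (log2 changes of -0.86 and -0.99), NAP1L1 and HNRNPA1 are in this list but are not translation genes, and NAP1L1 and HNRNPA1 did not pass. By contrast, 71 mitochondrial ribosomal proteins had a median of 0.261 (camera adjusted p = 0.077 over the added lists alone), above the 0.144 of all genes. A change shared by RNAs with a TOP motif is therefore a candidate explanation, and a change of both ribosomes is not.

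The histone list was called lower in 3D, though not with an estimated correlation (camera adjusted p = 0.659). Carry-over of RNA without a poly(A) tail into the 2D libraries was looked for in small RNA genes. Their RPM in 2D were 0.71 times those in 3D, with overlapping libraries (625.9 to 940.8 against 828.4 to 1409), so no excess in 2D was seen. Small RNA genes are another class than histone genes, so carry-over of histone RNA is not excluded. Reads shared among copies do not account for the fall of H2A and H1 genes, whose summed RPM in 3D were 0.345 and 0.319 times those in 2D. For H2B genes the summed reads were 0.85 times those in 2D with overlapping libraries (159.6 to 193.0 against 192.6 to 216.1), so sharing of reads between H2B copies may account for part of the fall of single H2B genes. A rise of polyadenylated histone transcripts in cells that have left the cycle was not tested.

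Further hypotheses were tested on lists written after the calls were seen, with p-values adjusted over the added lists alone. Of 24 FOXO targets and quiescence genes, 14 fell in 3D and 1 rose (median -0.644, camera adjusted p = 0.000164, and 0.454 with an estimated correlation). TXNIP and DEPP1 were left out of this list, but 8 members, GABARAPL1 among them, are in lists described before. Of the 16 others 11 fell and 1 rose (median -0.822), and a more quiescent flat culture may be a candidate explanation that was not tested on other data. Of 21 nucleotide synthesis genes outside the glutamine list, 11 rose and 1 fell (median 0.41). Their camera adjusted p was 0.048 over the added lists alone (unadjusted p = 0.04) and 0.528 with an estimated correlation. Among the 18 in no list fixed beforehand, 9 rose and 1 fell (median 0.295). Of 19 cytosolic tRNA synthetases, 14 rose and none fell (median 0.577, camera adjusted p = 0.00157, and 0.454 with an estimated correlation). Among the 12 in no list fixed beforehand, 8 rose and none fell (median 0.625). The nucleotide list with its members of the glutamine list had 16 of 27 higher and 1 lower (adjusted p = 0.00622, and 0.454 with an estimated correlation). Several of these genes are also in the ATF4, replication or one-carbon lists, so they are not independent evidence, and a difference in growth state between the cultures may underlie all of them.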
